A study of Mus musculus with 18 samples.

How the data were processed

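Total RNA from the tibialis anterior muscle of 2-month-old mice was measured on 18 Illumina bead arrays, 3 for each combination of strain (A/JOlaHsd, A/J or A/J-MyD88) and injection (saline or ssRNA). Per the labels, RNA was extracted with Trizol and checked on an Agilent Bioanalyser, and biotinylated cRNA was made with the Ambion Illumina TotalPrep kit. The label field of the samples names the dye Cy3. The animals behind the arrays, the batches and the chips are not given in the sources used here.

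The deposited intensity values came in 2 tables. The first holds the probe intensities that the authors exported from GenomeStudio, with no version stated, without normalization. In the second, the deposited intensities are on a linear scale and, by their columns, were quantile-normalized within the 6 arrays of each strain, with column medians of 0.965 to 1.01 in A/JOlaHsd, 3.84 to 3.87 in A/J and 3.12 to 3.14 in A/J-MyD88. That table was normalized per strain, so it was used only as an alternative. It served only for comparisons of legs within a strain and of these responses between strains. The detection p-value of each probe and array was deposited beside the first table and moves in steps of 1 in 936, the rank of the intensity among negative control beads.

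The first table was processed in R 4.3.3 with limma 3.58.1. Background was corrected and arrays were quantile-normalized together with neqc, which took its background parameters from the detection p-values and added an offset of 16 before the log2 step. Probes with a detection p under 0.05 on at least 3 arrays were kept, 20825 of 45281. Gene symbols came from the platform's annotation and were matched by Entrez ID to the mouse gene table of assembly GRCm38.p6, which changed 0 of 34807 matched symbols. Of all probes, 34885 had 1 symbol, 18 had several and 10378 were not listed, and the last 2 kinds were left out of the gene tests. The probe with the highest mean log2 value stood for each gene, which gave 11233 genes.

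A linear model with a mean per group was fitted to the log2 values (lmFit, eBayes), with 11 residual degrees of freedom from the arrays and 5.01 from the prior. P values were two-sided, adjusted by Benjamini and Hochberg over the genes of a comparison, and called under 0.05. Errors of differences are standard errors of this fit, and ± beside a group's value is the SD between arrays. The median standard error was 0.16 for comparisons within A/J, within A/J-MyD88 and between saline legs, 0.18 within A/JOlaHsd, and 0.25 and 0.23 for the response of A/J against A/JOlaHsd and of A/J-MyD88 against A/J. In a test on simulated data with 200 changed genes, 73, 77 and 82 of 100 genes changed 2-fold were called within A/JOlaHsd, A/J and A/J-MyD88, and 42 and 49 of 100 for the response differences. With 4-fold changes, 98, 99, 98, 92 and 93 of 100 were called. The simulation gave each gene the same spread in all strains and independent arrays. The lowest rank correlation between arrays was 0.729 in A/JOlaHsd, against 0.889 in A/J and 0.883 in A/J-MyD88. The shares that involve A/JOlaHsd may therefore be too high.

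Where a gene was above background on no array of the lower group, by any of its probes, the difference is given as a lower bound. It is the mean of the higher group over the lower group's values, raised to the smallest value detected on each array. The genes to be named, by rule, and the gene lists were fixed before the data were examined. The rule took Dysf and Myd88, the 8 largest increases and 8 largest decreases among called genes whose groups did not overlap (for response differences, among called genes), and up to 4 members of each described list. The members were called genes with the largest changes, or the 2 largest where none was called. Genes with only a clone or predicted name were passed over.

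The 29 gene lists cover interferon-induced genes, Toll-like receptor pathway components, cytokines and chemokines, antigen presentation, complement, inflammasome components, muscle regeneration, extracellular matrix, slow and fast fibres, mitochondrial respiration, glycolysis and glycogen, fatty acid oxidation, membrane repair, atrophy and autophagy, proliferation, immediate early and heat shock genes, erythroid genes, skin epithelium, neighbours of Myd88 on chromosome 9, and markers of macrophages, neutrophils, T and NK cells, B and plasma cells, fibroblasts, adipocytes, Schwann cells, endothelium and smooth muscle. They were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry beside it. Fry tests whether the genes of a list move one way on balance, not whether they differ from other genes. With the preset correlation, the estimated correlation and fry, 5, 1 and 1 lists were called in A/JOlaHsd, 16, 7 and 20 in A/J, 8, 0 and 0 in A/J-MyD88, 14, 0 and 16 for the response of A/J against A/JOlaHsd, and 17, 6 and 18 for that of A/J-MyD88 against A/J. In saline legs, 7, 0 and 18 were called for A/J against A/JOlaHsd and 11, 0 and 13 for A/J-MyD88 against A/J.

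The planned fit included all 18 arrays. A/JOlaHsd ssRNA array 2 was seen to hold no signal before any test was run, with 311 of 45281 probes at a detection p under 0.01 where chance gives 452.81. The decision to give values from 17 arrays was made after the counts of both fits had been seen, and the counts of the planned fit stand beside them. Of 8 comparisons, 7 were planned, and the comparison of ssRNA legs of A/J-MyD88 and A/J was added after the data were seen.

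Whether equal replicate numbers mark the 2 legs of 1 animal was checked by correlating, across genes, the residuals of saline and ssRNA arrays of a strain. The r of equal numbers was 0.40, 0.44 and 0.14 in A/J and 0.47, 0.17 and 0.17 in A/J-MyD88, each above 0.1, and -0.13 and -0.11 in A/JOlaHsd. The r of unequal numbers was -0.49 to 0.17 in A/J, -0.31 to 0.088 in A/J-MyD88 and -0.0092 to 0.13 in A/JOlaHsd. In A/J, the highest of these lay above the lowest r of equal numbers. With 2 ssRNA arrays, the residuals of A/JOlaHsd mirror each other, so the check decides little there. The plan was unblocked, and a fit with the replicate number as a paired block was run as an alternative. It gave 226, 2595 and 0 genes (212 unadjusted) in A/JOlaHsd, A/J and A/J-MyD88, 1127 and 1145 for the response differences, 5303 and 611 for the saline legs and 625 for the added comparison.

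Further settings were all 18 arrays, no background correction, centring on array medians in place of quantile normalization, no filter or a stricter filter (detection p under 0.01) on dim probes, every probe in place of 1 per gene, only the arrays compared, the authors' normalized values, an estimated correlation for the lists, and leaving out each array in turn. Normalization of each strain alone was added after the data were seen. Figures were drawn with Python 3.11.15.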

Results

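The tibialis anterior, a muscle at the front of the lower leg, was profiled in 2-month-old mice of 3 strains on Illumina bead arrays. A/JOlaHsd mice are labelled wild-type and dysferlin sufficient, A/J mice are labelled dysferlin deficient, and A/J-MyD88 mice are labelled deficient for both dysferlin and MyD88. Dysferlin is a membrane repair protein of muscle fibres, and MyD88 is the adaptor through which most Toll-like receptors signal. The muscle of one leg had received single-stranded RNA (ssRNA), a ligand of the endosomal receptor TLR7, and the opposite leg had received saline, in 3 injections within 10 days. Each strain and treatment had 3 arrays, 18 in all. The labels do not say whether each array was a separate animal, so the error between arrays does not separate technical from animal variation, and the small number of arrays limits the precision.

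A/JOlaHsd ssRNA array 2 held no signal from muscle. Its mean signal was -0.33 and its highest was 88.7, against mean signals of 37.4 to 50.2 on the other A/JOlaHsd arrays. It detected 3.71% of 45281 probes at a detection p under 0.05, and its highest rank correlation with any other array was 0.00258. The values below come from the other 17 arrays, which leaves 2 arrays of ssRNA legs in A/JOlaHsd. The planned fit kept all 18 arrays, and its counts are given beside those of 17. The choice was made after both had been seen.

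Signal was lower on the A/JOlaHsd arrays than on those of the other strains, whose ranges overlapped. The mean signal was 37.4 to 50.2 in A/JOlaHsd, 120.5 to 147.3 in A/J and 98.1 to 140.3 in A/J-MyD88, and 28.9% to 33.2%, 37.2% to 42.4% and 39.0% to 42.6% of probes were detected. Within a strain, the lowest rank correlation between arrays was 0.729, 0.889 and 0.883. The labels name no run or chip, so strain and this difference in signal cannot be told apart in comparisons of A/J with A/JOlaHsd. The tests covered 11233 genes.

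**Figure D1:**
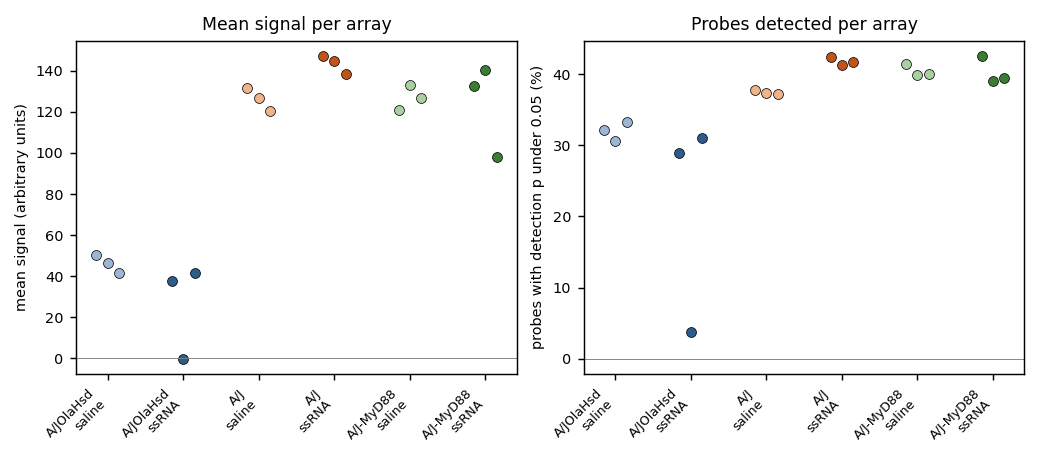
Mean signal (arbitrary units) and probes detected at p under 0.05 (percent of 45281) for each of the 18 arrays, coloured by strain, with saline and ssRNA legs as separate points. A/JOlaHsd ssRNA array 2 lies at a mean signal of -0.33 and 3.71% detected, and the other A/JOlaHsd arrays lie below those of A/J and A/J-MyD88.

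The genes that the strains differ in by design were read first. Dysf, the dysferlin gene, stood at a log2 value of 9.60 ± 0.16 (SD, n = 3) in A/JOlaHsd saline legs, 6.13 ± 0.08 in A/J and 6.15 ± 0.26 in A/J-MyD88. It was lower in A/J than in A/JOlaHsd by a log2 difference of -3.47 ± 0.14 (SE, adjusted p = 1.32e-10). Among 3 further Dysf probes, 2 were also lower, by -2.10 and -2.43 (adjusted p over all probes = 1.41e-07 and 6.67e-09), and 1 was higher by 0.81 (adjusted p = 0.000860). Myd88 was higher in A/J-MyD88 than in A/J saline legs on its main probe (0.71 ± 0.17, adjusted p = 0.0203), and a second probe differed by 0.06 (adjusted p = 0.898). The positions of these probes relative to the targeted part of Myd88 are not given in the sources used here, so their values do not test the loss of MyD88.

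The response of dysferlin-deficient muscle to ssRNA was read in A/J. Macrophage markers, cytokines and chemokines, and antigen presentation genes were higher in the legs given ssRNA, and kept their list calls with an estimated correlation. Lyz2, the lysozyme of macrophages and neutrophils, stood at a log2 value of 11.39 ± 0.36 (SD, n = 3) against 7.99 ± 0.43 in saline legs (log2 fold change 3.40 ± 0.45 (SE), adjusted p = 6.72e-05). Ccl8, a chemokine that attracts monocytes, reached 8.52 ± 0.45 against 4.73 ± 0.26, a rise of 3.79 ± 0.28 (adjusted p = 9.88e-07), with 2 of 3 saline arrays above background. The interferon-induced gene Ifi27l2a reached 10.15 ± 0.40 against 6.53 ± 0.38, a rise of 3.62 ± 0.30 (adjusted p = 1.90e-06). Of 11233 genes, 1394 were higher and 1124 lower, 2518 in all. More than 2-fold changes were found in 550 of the higher and 41 of the lower genes. The 18 arrays gave 220 genes (207 higher and 13 lower). The count was 1537 without A/J saline array 3 (1013 higher and 524 lower). With median centring, the split was 2486 higher and 345 lower.

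The other largest rises in A/J were of Fcer1g (4.12 ± 1.09), the signalling chain of Fc receptors, Ms4a6d (3.63 ± 0.44), the Fc receptor Fcgr4 (3.57 ± 0.33), Plac8 (3.45 ± 0.35) and Ms4a7 (3.45 ± 0.34), with adjusted p values of 5.20e-06 to 0.0124. For Fcer1g, the saline legs varied widely (5.64 ± 1.28, SD, 2 of 3 arrays above background), and its adjusted p was 0.0621 without A/J saline array 1. The largest falls were of Pdk2 (-1.56 ± 0.30), a kinase of pyruvate dehydrogenase, the lactate transporter gene Slc16a3 (-1.46 ± 0.28), Fitm1 (-1.41 ± 0.26), which acts in lipid droplet formation, Crat (-1.30 ± 0.19), the carnitine acetyltransferase, the amino acid transporter gene Slc38a3 (-1.28 ± 0.24), Wnt4 (-1.34 ± 0.18), Atg9a (-1.26 ± 0.15), a membrane protein of autophagy, and the slow myosin light chain gene Myl3 (-1.25 ± 0.28). The adjusted p values of these 8 genes were 3.20e-05 to 0.00482. Myd88 itself rose by 1.25 ± 0.17 (adjusted p = 8.14e-05), and by 0.68 ± 0.13 on a second probe (adjusted p over all probes = 0.00238). Dysf fell by 0.43 ± 0.14 (adjusted p = 0.0365), from 6.13 ± 0.08 to 5.70 ± 0.09, and none of 3 further Dysf probes was called (0.105 to 0.915). The call on the main probe ended with any 1 of the 6 A/J arrays left out, with an adjusted p of 0.0859, 0.0978 and 0.0640 without saline arrays 1, 2 and 3 and of 0.100, 0.0512 and 0.118 without ssRNA arrays 1, 2 and 3.

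Of 29 gene lists tested with limma's camera, 16 moved in A/J. Of 30 measured macrophage markers, 27 rose (29 adjusted over the list alone), with a median log2 fold change of 2.59 and a list adjusted p of 6.33e-26. Ctss, the lysosomal protease cathepsin S, rose by 3.12 ± 0.30 among them. Of 27 antigen presentation genes, 21 rose (22 adjusted over the list alone, median 1.41, list adjusted p = 6.80e-16), with H2-Ab1 at 2.33 ± 0.28, Cd74, the invariant chain of class II molecules, at 2.24 ± 0.30, and H2-D1 at 2.21 ± 0.23. Of 32 interferon-induced genes, 16 rose (24 adjusted over the list alone, median 0.97, list adjusted p = 6.59e-10 and 0.176 with an estimated correlation), with Lgals3bp at 2.31 ± 0.24, Oasl2 at 2.04 ± 0.41 and Irf7, a transcription factor of the interferon response, at 1.92 ± 0.33. Of 32 cytokines and chemokines, 16 rose (18 adjusted over the list alone, median 0.60, list adjusted p = 6.20e-10), with Ccl9 at 2.69 ± 0.28 and Ccl5 at 2.47 ± 0.21. The adjusted p values of the genes in this paragraph were 2.02e-06 to 0.00211.

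Components of the Toll-like receptor pathway also rose in A/J, 16 of 32, while 3 fell (16 and 4 adjusted over the list alone, median 0.38, list adjusted p = 4.67e-06). Tlr13, a receptor for bacterial RNA, rose by 2.48 ± 0.40, Tlr7, the receptor for ssRNA, by 2.14 ± 0.24, Unc93b1, which carries endosomal Toll-like receptors to their compartment, by 1.97 ± 0.32, and Tlr2 by 1.84 ± 0.20 (adjusted p = 1.52e-05 to 0.000365). Of 17 T and NK cell markers, 8 rose (8 adjusted over the list alone, median 0.51, list adjusted p = 7.41e-06). The NK receptor gene Klrd1 rose by 2.40 ± 0.17 (adjusted p = 6.85e-07), with 1 of 3 saline arrays above background, and Nkg7, not above background in saline legs, was at least 2.58-fold higher (adjusted p = 1.01e-05). Of 14 complement genes, 10 rose (10 adjusted over the list alone, median 1.12, list adjusted p = 1.29e-06 and 0.0581 with an estimated correlation), among them C1qb (2.75 ± 0.33) and C1qc (2.67 ± 0.28), chains of the first complement component. Of 6 neutrophil markers, 4 rose (5 adjusted over the list alone, median 0.62, list adjusted p = 0.000399 and 0.0713 with an estimated correlation), and Fpr2, a receptor for formyl peptides that was not above background in saline legs, was at least 3.24-fold higher (adjusted p = 1.77e-06). Of 17 inflammasome components, 9 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.50, list adjusted p = 4.67e-05), with Casp1 at 2.25 ± 0.24 (adjusted p = 1.25e-05).

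Genes of cell division and tissue remodelling rose in the same A/J legs. Of 26 proliferation genes, 18 rose (19 adjusted over the list alone, median 0.89, list adjusted p = 1.14e-12), among them Prc1 (2.40 ± 0.35) and Cdc20 (1.58 ± 0.20), which act in mitosis, and Cdk1, not above background in saline legs, was at least 2.65-fold higher (adjusted p = 3.97e-05 to 0.00128). Of 38 extracellular matrix genes, 27 rose (30 adjusted over the list alone, median 1.07, list adjusted p = 1.23e-15 and 0.112 with an estimated correlation), with Tnc, tenascin C, at 2.48 ± 0.32, Fn1, fibronectin, at 2.26 ± 0.42 and Thbs2 at 1.93 ± 0.26 (adjusted p = 5.24e-05 to 0.00114). Of 24 muscle regeneration genes, 8 rose (11 adjusted over the list alone, median 0.79, list adjusted p = 4.87e-06 and 0.168 with an estimated correlation), including Vim (2.21 ± 0.18), Mest (1.83 ± 0.29) and Myog (1.69 ± 0.34), a transcription factor of differentiating myoblasts (adjusted p = 1.90e-06 to 0.00227). Of 19 fibroblast markers, 8 rose (10 adjusted over the list alone, median 0.65, list adjusted p = 4.67e-06 and 0.116 with an estimated correlation), with Col14a1 at 1.28 ± 0.21 (adjusted p = 0.000470).

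In A/J, 3 lists of energy metabolism were lower, each called with the preset correlation alone. Of 44 mitochondrial respiration genes, 12 fell (16 adjusted over the list alone, median -0.35, list adjusted p = 1.66e-06 and 0.223 with an estimated correlation). Ogdh, of the citric acid cycle, fell by 0.72 ± 0.18 (adjusted p = 0.00873, and 0.0510 without A/J ssRNA array 1), and Uqcrc1, a subunit of complex III, by 0.61 ± 0.12 (adjusted p = 0.00200). Of 25 fatty acid oxidation genes, 5 fell (5 adjusted over the list alone, median -0.38, list adjusted p = 0.00128 and 0.223 with an estimated correlation), Decr1 by 1.06 ± 0.19 (adjusted p = 0.000733). Of 23 glycolysis and glycogen genes, 5 fell (5 adjusted over the list alone, median -0.20, list adjusted p = 0.0326 and 0.158 with an estimated correlation). Pygm, the glycogen phosphorylase of muscle, fell by 1.08 ± 0.21 (adjusted p = 0.00186). The glycolysis list had an adjusted p of 0.0595 without A/J saline array 1 and of 0.0673 without A/J ssRNA array 2. It stood at 0.0629 with the authors' values, 0.0681 with each strain normalized alone, 0.0884 with only the compared arrays and 0.263 with 18 arrays, which put mitochondrial respiration at 0.0825.

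The 13 lists without a call in A/J had list adjusted p values of 0.0525 to 0.799. They were B and plasma cells (3 of 7 genes higher, median 0.33, list adjusted p = 0.0525), slow fibres (0.799), fast fibres (0.308), membrane repair (0.287), atrophy and autophagy (0.430), immediate early and heat shock genes (0.210), adipocytes (0.732), Schwann cells (0.297), endothelium (0.275), smooth muscle (0.125), erythroid genes (0.125), skin epithelium (0.732) and neighbours of Myd88 (0.142). Membrane repair genes had a median of -0.04 and a mean of 0.18, and adipocyte markers a median of -0.05, a mean of 0.04 and a downward test. Single members passed the test, among them Mylk2, the myosin light chain kinase of skeletal muscle (-0.58 ± 0.11), Abcc9 of smooth muscle (-0.93 ± 0.18) and Sox10 of Schwann cells (-0.80 ± 0.16), with adjusted p values of 0.00127 to 0.00211. The endothelial gene Ly6c1 rose by 0.72 ± 0.20 (adjusted p = 0.0163), which became 0.0631 without A/J saline array 1 and 0.0832 without A/J ssRNA array 1. The endothelial gene Gpihbp1 fell by 0.65 ± 0.22 (adjusted p = 0.0443). Its adjusted p was 0.0926 and 0.163 without A/J saline arrays 2 and 3, 0.0909 and 0.174 without A/J ssRNA arrays 1 and 3, and 0.101 with a replicate block. Among the genes named for A/J, median centring ended the calls of Dysf (0.509), Gpihbp1 (0.179) and Uqcrc1 (0.0568), no background correction those of Fcer1g (0.133), Gpihbp1 (0.079) and Mest (0.0786), and no filter that of Gpihbp1 (0.0891). With 18 arrays, 35 ended (0.0540 to 1.00). In every called gene named for A/J, all ssRNA arrays lay on 1 side of all saline arrays.

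**Figure D2:**
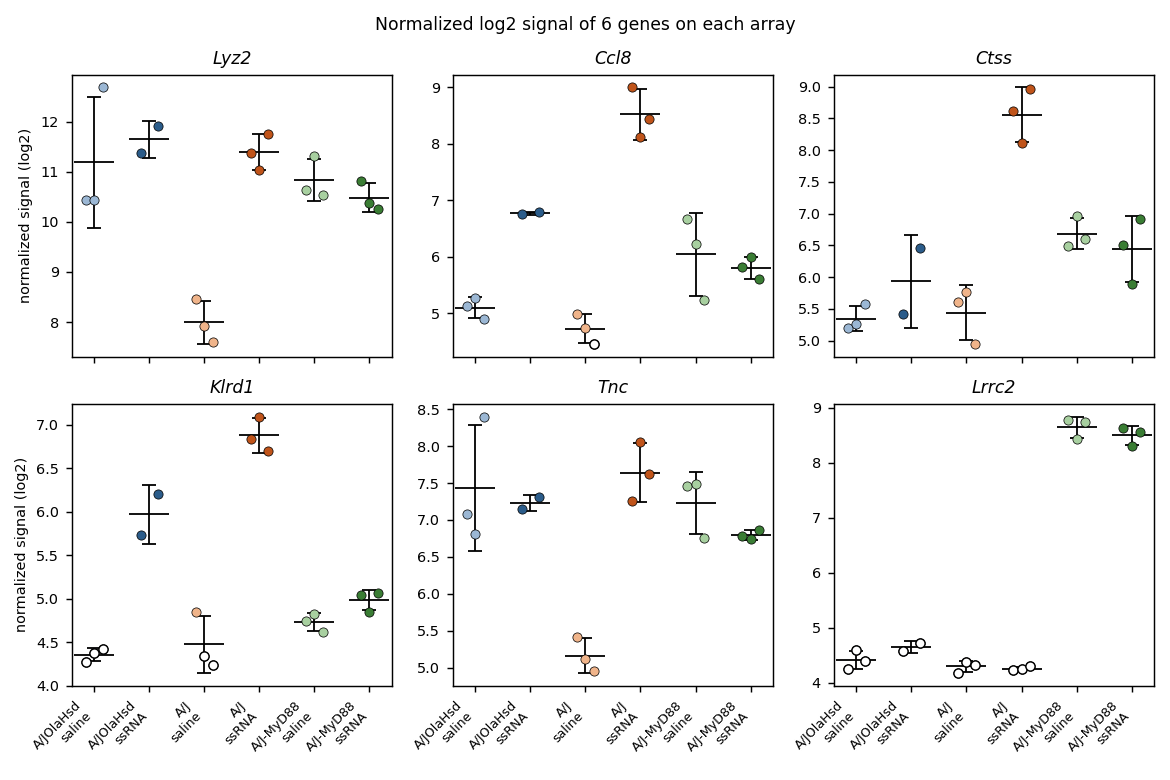
Log2 normalized signal of Lyz2, Ccl8, Ctss, Klrd1, Tnc and Lrrc2 on each of the 17 arrays, by strain and treatment; lines are group means, error bars are SD, and open circles mark values not above background. Lyz2 rises from 7.99 to 11.39 in A/J and stands at 10.83 in A/J-MyD88 saline legs, and Lrrc2 stands at 8.65 in A/J-MyD88 and 4.30 in A/J saline legs.

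The response of muscle deficient for both dysferlin and MyD88 was read in A/J-MyD88. No gene passed the test in limma (0 of 11233 genes, 131 at an unadjusted p under 0.05, smallest adjusted p = 1.00), and the 18 arrays gave 0 genes as well (20 unadjusted). Lyz2 stood at 10.48 ± 0.30 in ssRNA legs and 10.83 ± 0.42 in saline legs (SD, n = 3), a difference of -0.35 ± 0.45 (SE). Among list members, Ankrd1 differed by -1.30 ± 0.41, Myh8, the perinatal myosin gene, by 1.25 ± 0.39, Myl2, of slow fibres, by 1.10 ± 0.81, and Gadd45a by -1.07 ± 0.38. The interferon-induced genes Ifit3 and Ifit2 differed by 1.05 ± 0.62 and 0.74 ± 0.48. Tnnc1, Gpnmb, Klrd1, Prc1 and Cryab differed by 0.76 ± 0.33, 0.43 ± 0.43, 0.25 ± 0.17, -0.34 ± 0.35 and -0.49 ± 0.17. Myd88 differed by 0.09 ± 0.17 and Dysf by -0.01 ± 0.14. All these adjusted p values were 1.00.

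With a preset correlation, 8 lists moved in A/J-MyD88, though no member of any passed the test over all genes. Interferon-induced genes (median 0.27, list adjusted p = 1.55e-05), slow fibre genes (0.29, 7.91e-05), extracellular matrix genes (0.15, 0.0178) and regeneration genes (0.11, 0.0329, and 0.0992 with a replicate block) were higher. Proliferation genes (-0.15, 7.91e-05), immediate early genes (-0.10, 0.00266), erythroid genes (-0.30, 0.0168) and atrophy genes (-0.07, 0.0238) were lower. With an estimated correlation, none was called (adjusted p = 0.198 to 0.795), nor with fry. Macrophage markers had a median of -0.07 (list adjusted p = 0.314). Each of the 8 calls ended when A/J-MyD88 ssRNA array 3 was left out, with a list adjusted p of 0.0571 for proliferation, immediate early, atrophy and slow fibre genes, 0.275 for erythroid and matrix genes, 0.322 for interferon-induced genes and 0.829 for regeneration genes. Without saline array 1, erythroid and immediate early genes stood at 0.143. Without saline array 2, proliferation genes stood at 0.104 and atrophy genes at 0.219. Without saline array 3, matrix genes reversed their direction (0.423), and atrophy and regeneration genes stood at 0.183 and 0.863. Without ssRNA array 1, atrophy genes stood at 0.362, and without ssRNA array 2, matrix and regeneration genes stood at 0.121 and 0.0562. Regeneration genes stood at 0.128 with the authors' values, 0.135 with each strain normalized alone, 0.116 with no background correction, 0.074 with no filter, 0.497 with only the compared arrays and 0.449 with 18 arrays. Atrophy genes stood at 0.0595, 0.0625, 0.0688 and 0.0611 with each strain alone, no background correction, no filter and 18 arrays, and at 0.0515 with median centring. Erythroid genes stood at 0.0595, 0.138, 0.114 and 0.292 with each strain alone, median centring, no filter and 18 arrays, and matrix genes at 0.0595 and 0.262 with each strain alone and 18 arrays.

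The difference between the responses of A/J-MyD88 and A/J was tested directly. Macrophage and chemokine genes rose in A/J, while no gene was called in A/J-MyD88. The response of Ccl8 was lower by -4.03 ± 0.40 (SE, adjusted p = 0.000113), that of Lyz2 by -3.74 ± 0.64 (adjusted p = 0.00182) and that of Ctss by -3.37 ± 0.43 (adjusted p = 0.000353). The test found 375 genes with a higher and 769 with a lower response, 1144 in all, against 25 (0 higher and 25 lower) with 18 arrays. The count was 652, 760 or 599 without A/J saline array 3, A/J ssRNA array 3 or A/J-MyD88 saline array 2. With median centring it was 1764 (83 higher and 1681 lower, median of all genes -0.14). It was 2174 with only the compared arrays (969 higher and 1205 lower) and 2131 with the authors' values. The saline legs of the strains were not alike. The mean macrophage list score was -1.12 ± 0.32 (SD) in A/J saline, 1.23 ± 0.21 in A/J ssRNA, 0.23 ± 0.31 in A/J-MyD88 saline and 0.18 ± 0.08 in A/J-MyD88 ssRNA legs.

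Other genes with a lower response in A/J-MyD88 were Ms4a6d (-3.79 ± 0.63), H2ac12 (-3.65 ± 0.46), Ifi27l2a (-3.64 ± 0.43), H2ac15 (-3.63 ± 0.60) and Ms4a7 (-3.53 ± 0.48), where the H2ac genes encode histone H2A (adjusted p = 0.000243 to 0.00160). The responses of Tlr7 (-2.20 ± 0.34), Tlr2 (-1.99 ± 0.29), Ccl9 (-2.92 ± 0.40), Tnc (-2.91 ± 0.45), H2-D1 (-2.17 ± 0.33), Psmb8 (-2.17 ± 0.34), a subunit of the immunoproteasome, Lgals3bp (-2.01 ± 0.34), Ifitm3 (-1.35 ± 0.27), Cdc20 (-1.80 ± 0.28) and Mcm5 (-1.64 ± 0.22), of DNA replication, were lower as well (adjusted p = 0.000521 to 0.00458). So were those of Klrd1 (-2.15 ± 0.23, adjusted p = 0.000128) and of Nkg7 (adjusted p = 0.00130, and 0.12 with no background correction), whose size was not measured, since Nkg7 was not above background in A/J saline legs. The response of Myd88 was lower by -1.17 ± 0.24 (adjusted p = 0.00578), with a second probe at -0.55 not called (adjusted p over all probes = 0.0924), and that of Dysf differed by 0.42 ± 0.20 (adjusted p = 0.211). Slc16a3 (1.65 ± 0.39), Pdk2 (1.60 ± 0.43), Fitm1 (1.48 ± 0.37), Chrne (1.47 ± 0.29), a subunit of the acetylcholine receptor at the adult neuromuscular junction, Decr1 (1.42 ± 0.26), Slc38a3 (1.40 ± 0.34), Crat (1.34 ± 0.27) and Lrtm1 (1.32 ± 0.33) had a higher response (adjusted p = 0.00308 to 0.0264). Of these, Pdk2 ended at an adjusted p of 0.0654 without A/J saline array 1, 0.0689 and 0.0741 without A/J ssRNA arrays 1 and 3, 0.0582 and 0.0833 without A/J-MyD88 saline arrays 1 and 2 and 0.0692 without A/J-MyD88 ssRNA array 3. Fitm1 ended at 0.0563 without A/J saline array 3 and 0.0564 without A/J-MyD88 saline array 2, and Lrtm1 at 0.0565 without the latter. Lrtm1 stood at 0.0517 with median centring, and Pdk2 at 0.0603 with no background correction and 0.0649 with no filter. With 18 arrays, 27 of the calls named for this difference ended (0.0544 to 1.00).

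Among the lists, 17 differed between these responses. Macrophage markers (23 of 30 lower, 28 adjusted over the list alone, median -2.52, list adjusted p = 5.60e-27), antigen presentation (17 of 27, 20, -1.35, 3.70e-15), proliferation (15 of 26, 18, -1.12, 6.50e-15), cytokines (11 of 32, 14, -0.63, 6.43e-10), Toll-like receptor components (13 of 32, 16 lower and 2 higher, -0.50, 3.37e-06) and T and NK cell markers (6 of 17, 7 lower and 1 higher, -0.44, 5.66e-05) were lower, and these 6 kept their calls with an estimated correlation (adjusted p = 0.0254 to 0.0353). The calls of matrix genes (1.79e-11), complement (3.37e-06), interferon-induced genes (1.28e-05), fibroblast markers (3.11e-05), neutrophil markers (0.000408), inflammasome components (0.000481), regeneration (0.00156), B and plasma cells (0.0293) and immediate early genes (0.0420) to the lower side, and of mitochondrial respiration (7.94e-06) and fatty acid oxidation (0.00452) to the higher side, were lost (adjusted p = 0.0684 to 0.291 with an estimated correlation). B and plasma cells stood at 0.0858 with a replicate block, 0.0640 without A/J saline array 2, and 0.0728 and 0.0632 without A/J ssRNA arrays 2 and 3. Immediate early genes stood at 0.0681 with a replicate block, 0.121 without A/J-MyD88 saline array 1, 0.0909 without A/J saline array 2, and 0.0676 and 0.0591 without A/J ssRNA arrays 2 and 3. Median centring put them at 0.136 for B and plasma cells and 0.101 for immediate early genes, only the compared arrays put B and plasma cells at 0.0506, and no background correction and the stricter filter put immediate early genes at 0.0673 and 0.0702. With 18 arrays, both ended (0.615 and 0.0539), as did fatty acid oxidation (0.0553) and mitochondrial respiration (0.130).

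**Figure D3:**
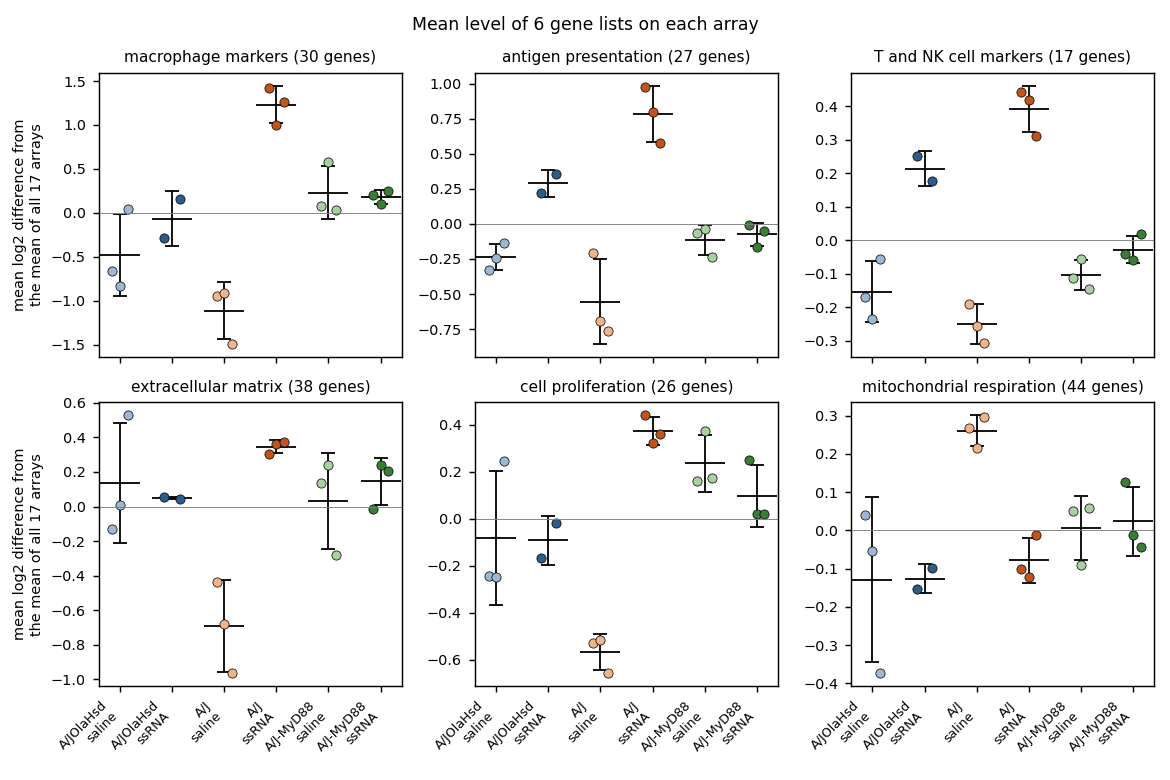
List score of each of the 17 arrays (mean over list members of the log2 value minus that member's mean over the 17 arrays) by strain and treatment; lines are group means and error bars are SD. The macrophage score is -1.12 in A/J saline, 1.23 in A/J ssRNA, 0.23 in A/J-MyD88 saline and 0.18 in A/J-MyD88 ssRNA legs.

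The response of muscle with dysferlin was read in A/JOlaHsd, from 2 ssRNA and 3 saline arrays. The chemokine genes Ccl8 and Ccl5 and genes of NK cells were higher in ssRNA legs, while cytokines and chemokines as a list were not (list adjusted p = 0.898). Ccl8 stood at 6.77 ± 0.03 (SD, n = 2) against 5.10 ± 0.19 (n = 3), a log2 fold change of 1.67 ± 0.32 (SE, limma adjusted p = 0.0140). Klrd1 and Ccl5, not above background in saline legs, were at least 2.27-fold and 2.39-fold higher (adjusted p = 0.000654 and 0.00251), and Nkg7 rose by 1.58 ± 0.17, from 4.57 ± 0.26 to 6.14 ± 0.23 (adjusted p = 0.000603). Nkg7 was above background on 1 of 3 saline arrays. The test found 103 higher and 110 lower genes, 213 in all, with 32 and 27 of them changed more than 2-fold. The 18 arrays gave 28 (5 higher and 23 lower). Without saline arrays 1 or 3 the count was 357 or 516, and without ssRNA arrays 1 or 3, which leaves 1 array in that group, it was 461 (273 higher and 188 lower) or 384. It was 0 in limma with median centring (730 unadjusted), each strain normalized alone (510), only the compared arrays (253) and the authors' values (452).

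Further rises in A/JOlaHsd were of Fcgr4 (1.76 ± 0.37, adjusted p = 0.0236), Clec4b1 (1.44 ± 0.24, 0.00769), Cd53 (1.35 ± 0.28, 0.0208) and the immunoproteasome gene Psmb10 (0.84 ± 0.20, 0.0451, and a log2 fold change of -0.33 with 18 arrays). Fcgr4 was above background on 2 of 3 saline arrays and Cd53 on 1 of 3. Ctsw, a protease of NK and cytotoxic T cells, and Naip5, a sensor of flagellin, were not above background in saline legs and at least 1.97-fold and 1.77-fold higher (adjusted p = 0.00172 and 0.00287). Among the lower genes, Ccdc137 fell by 1.24 ± 0.22, Pde4a by 1.20 ± 0.24 and the chemokine gene Cxcl1 by 1.10 ± 0.26 (adjusted p = 0.00893 to 0.0404). Each of these was above background on 1 of 2 ssRNA arrays. Not above background in ssRNA legs, Map3k14, Gtf2ird1, Pdcd6ip, Mical1, Tmcc2 and Aldh1a2 were at least 1.93-fold, 2.05-fold, 1.91-fold, 1.57-fold, 1.56-fold and 1.44-fold lower (adjusted p = 0.00215 to 0.0328). With a replicate block the adjusted p was 0.0541 for Aldh1a2, 0.0604 for Cd53, 0.0501 for Cxcl1 and 0.0817 for Psmb10. Dysf differed by -0.10 ± 0.16 on its main probe (adjusted p = 0.845), while 1 of 3 further Dysf probes was lower, by -0.75 ± 0.16 (adjusted p over all probes = 0.0223), and 2 were not called (0.221 and 0.857). Myd88 differed by 0.34 ± 0.19 (0.456, and a log2 fold change of -1.0 with 18 arrays), Tlr7 by 0.70 ± 0.27 (0.236), Ifit3 by 1.21 ± 0.70 (0.471), Ms4a7 by 1.04 ± 0.38 (0.213), Adgre1 by 1.02 ± 0.29 (0.0950) and Oasl2 by 1.08 ± 0.46 (0.297, and 0.0452 with a replicate block). In the called genes named here, both ssRNA arrays lay on 1 side of all saline arrays.

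Single arrays decided several of these calls in A/JOlaHsd. Without saline array 1, Cxcl1 stood at an adjusted p of 0.0514. Without saline array 2, Aldh1a2 and Cxcl1 stood at 0.0581 and 0.0617. Without saline array 3, Psmb10 stood at 0.0717, while Adgre1, Ms4a7 and Tlr7 passed at 0.0130, 0.0338 and 0.0134. Without ssRNA array 1, Aldh1a2, Cxcl1, Mical1 and Pde4a stood at 0.0805, 0.172, 0.0541 and 0.0874. Without ssRNA array 3, Aldh1a2, Cd53, Fcgr4 and Psmb10 stood at 0.0733, 0.0955, 0.0887 and 0.266. All 19 calls named for A/JOlaHsd ended with median centring, with each strain normalized alone and with the authors' values. With only the compared arrays in the fit 14 ended (adjusted p = 0.558 to 1.00). The others, Aldh1a2, Ccl5, Ctsw, Klrd1 and Naip5, did not pass the detection filter there and were not tested, so none of the calls held. With 18 arrays 11 ended (0.0582 to 0.714). Cxcl1, Fcgr4 and Psmb10 ended with no background correction (0.101, 0.0589 and 0.0616), Cxcl1 with no filter (0.0547) and Psmb10 with the stricter filter (0.0515).

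In A/JOlaHsd, 5 lists were higher in ssRNA legs. They were antigen presentation (1 of 27 genes higher, 11 adjusted over the list alone, median 0.59, list adjusted p = 1.79e-06), interferon-induced genes (0 of 32, 0, 0.38, 0.000481), macrophage markers (0 of 30, 2, 0.39, 0.000481), T and NK cell markers (2 of 17, 3, 0.28, 0.000481) and Toll-like receptor components (0 of 32, 0, 0.11, 0.0337). T and NK cell markers kept the call (adjusted p = 0.0402 with an estimated correlation, and 0.00102 with fry), and the others lost it (adjusted p = 0.482 to 0.891 with an estimated correlation). Macrophage markers stood at 0.0907 and Toll-like receptor components at 0.195 with a replicate block. Macrophage markers stood at 0.156 without saline array 2 and 0.356 without ssRNA array 3. Toll-like receptor components stood at 0.160 and 0.263 without saline arrays 1 and 2, and at 0.116 and 0.236 without ssRNA arrays 1 and 3. The latter list stood at 0.0967, 0.0611 and 0.138 with median centring, no background correction and no filter, and T and NK cell markers stood at 0.0560 with only the compared arrays. With 18 arrays, antigen presentation, macrophage markers and Toll-like receptor components stood at 0.102, 0.470 and 0.0897. Cytokines had a median of -0.07, a mean of 0.03 and a downward test (list adjusted p = 0.898).

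**Figure D4:**
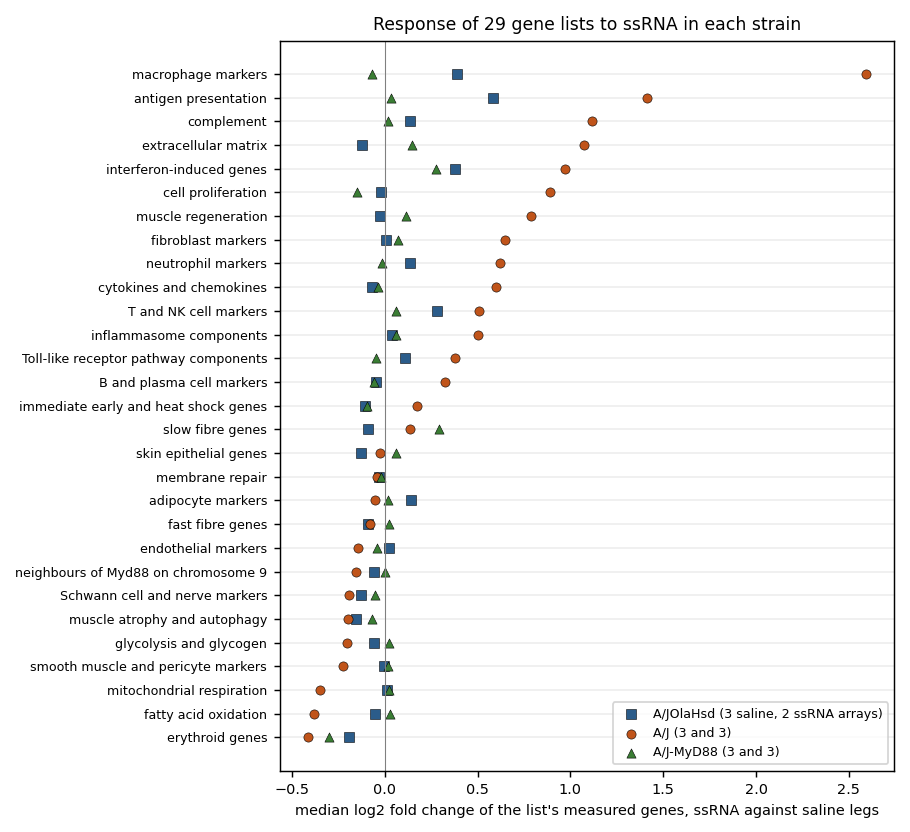
Median log2 fold change (ssRNA minus saline) of the members of each gene list in A/JOlaHsd, A/J and A/J-MyD88, 1 point per list and strain. Macrophage markers lie at 0.39, 2.59 and -0.07, and mitochondrial respiration lies at -0.35 in A/J.

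The responses of A/J and A/JOlaHsd were compared to ask how dysferlin deficiency goes with the size of the response, with the lower signal of the A/JOlaHsd arrays not separable from strain. Ifi27l2a responded more in A/J by 3.16 ± 0.45 (SE, adjusted p = 0.00340), Tnc by 2.67 ± 0.48 (adjusted p = 0.00759) and Ctss by 2.53 ± 0.45 (adjusted p = 0.00759), from 3 against 3 arrays in A/J and 2 against 3 in A/JOlaHsd. The test found 554 genes with a higher and 296 with a lower response in A/J, 850 in all, and 5 (5 higher and 0 lower) with 18 arrays. Without A/JOlaHsd saline array 1 the count was 1306, and without A/JOlaHsd ssRNA array 1 it was 536. It was 307, 448 or 382 without A/J saline array 3, A/J ssRNA array 1 or A/J ssRNA array 3. With median centring it was 1754 (1742 higher and 12 lower), where the median of all genes moved by 0.23. It was 830 with no filter (453 higher and 377 lower) and 187 with only the compared arrays (156 higher and 31 lower). The authors' values gave 1394. Of the genes called in A/J, 64.9% had the same sign in A/JOlaHsd and 44.0% in A/J-MyD88. The saline legs differed too. Lyz2 stood at 7.61 to 8.45 on A/J and 10.43 to 12.68 on A/JOlaHsd saline arrays, but at 11.03 to 11.75 and 11.38 to 11.91 on ssRNA arrays. Tnc stood at 4.95 to 5.42 and 6.81 to 8.40 on saline arrays, and at 7.26 to 8.05 and 7.15 to 7.31 on ssRNA arrays. For Ctss, saline arrays overlapped, and ssRNA arrays stood at 8.11 to 8.96 in A/J and 5.41 to 6.45 in A/JOlaHsd.

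Lyz2 (2.94 ± 0.67), Ms4a6d (2.85 ± 0.67), Gpnmb (2.85 ± 0.64), a glycoprotein of phagocytes, H2ac12 (2.68 ± 0.48) and Tyrobp (2.66 ± 0.55), an adaptor of myeloid receptors, also responded more in A/J (adjusted p = 0.00759 to 0.0202). The same held for Fn1 (2.52 ± 0.63), C1qb (2.38 ± 0.49), Ccl9 (2.17 ± 0.43), Col1a1 (2.09 ± 0.48), Prc1 (2.06 ± 0.52), Lgals3bp (1.73 ± 0.36), Tlr7 (1.44 ± 0.36) and Myd88 (0.91 ± 0.25), and, without a measure of size, for the neuropeptide gene Gal and for Ccl7, not above background in A/JOlaHsd ssRNA legs, and for Top2a, a topoisomerase of dividing cells not above background in A/J saline legs, with adjusted p values of 0.010 to 0.0402. The response was lower in A/J for Wscd1 (-1.59 ± 0.26), Asb12 (-1.57 ± 0.39), Otud6b (-1.53 ± 0.26), Leo1 (-1.51 ± 0.31), Fitm1 (-1.5 ± 0.39), Smc3 (-1.49 ± 0.26), a subunit of cohesin, S100a14 (-1.36 ± 0.30) and Wnt4 (-1.34 ± 0.27), with adjusted p values of 0.00499 to 0.0306. A second Myd88 probe, not above background in A/JOlaHsd, was not called (adjusted p over all probes = 0.117). Dysf differed by -0.33 ± 0.21 (adjusted p = 0.357), by 1.44 with 18 arrays and by 0.14 with median centring. With 18 arrays, all 27 of these calls ended (adjusted p = 0.0570 to 0.918). With only the compared arrays in the fit, 12 ended (Asb12, Fitm1, Fn1, Gpnmb, Leo1, Lyz2, Ms4a6d, Myd88, Prc1, S100a14, Tlr7 and Top2a, 0.0518 to 0.107), with no background correction 9 (Asb12, Fitm1, Gal, Leo1, Myd88, Prc1, S100a14, Smc3 and Tyrobp, 0.0515 to 0.0979), with no filter 7 (Asb12, Fitm1, Fn1, Gal, Myd88, Prc1 and Top2a, 0.0504 to 0.0736), with median centring 5 (Asb12, Fitm1, Leo1, S100a14 and Smc3, 0.0768 to 0.25), and with the authors' values S100a14 (0.117). Of the 27, 14 held with any single array left out. Without A/JOlaHsd ssRNA array 1, 13 ended (Asb12, Col1a1, Fitm1, Fn1, Gal, Gpnmb, Lyz2, Ms4a6d, Myd88, Prc1, Tlr7, Top2a and Tyrobp, adjusted p = 0.0505 to 0.142), and without A/J saline array 3, all of those but Tyrobp (0.0504 to 0.100). Without A/J ssRNA array 3, 7 ended (Asb12, Fitm1, Fn1, Ms4a6d, Prc1, Tlr7 and Top2a, 0.0505 to 0.0728), and without A/J ssRNA array 1, 6 (Fn1, Gal, Myd88, Prc1, Tlr7 and Top2a, 0.0516 to 0.0876). Without A/J ssRNA array 2, 5 ended (Fitm1, Gal, Myd88, Prc1 and Top2a, 0.0501 to 0.0752). Without A/J saline array 1, Fitm1, Gal and Top2a ended (0.0584 to 0.0659), without A/J saline array 2, Myd88 (0.0599), without A/JOlaHsd saline array 3, Fitm1, Gal and Myd88 (0.0511 to 0.0668), and without A/JOlaHsd ssRNA array 3, Asb12, Fitm1 and Fn1 (0.0562 to 0.0675).

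Among the lists, 14 differed between A/J and A/JOlaHsd in their response. Macrophage markers (22 of 30 genes higher, 24 adjusted over the list alone, median 1.99, list adjusted p = 7.00e-19), matrix genes (15 of 38, 28, 1.13, 4.57e-15), proliferation (12 of 26, 17, 1.00, 6.45e-12), cytokines (10 of 32, 14, 0.71, 2.63e-09), antigen presentation (5 of 27, 9, 0.84, 2.18e-07), regeneration (4 of 24, 5, 0.95, 5.33e-06), complement (5 of 14, 8, 0.99, 5.19e-05), fibroblast markers (3 of 19, 8, 0.76, 8.61e-05), interferon-induced genes (0.00138), inflammasome components (0.00223), Toll-like receptor components (0.00283) and neutrophil markers (0.0190) responded more in A/J. Mitochondrial respiration (median -0.35, 2.27e-05) and fatty acid oxidation (-0.38, 0.0236) responded less. None was called with an estimated correlation (adjusted p = 0.137 to 0.464). Interferon-induced genes stood at 0.102 without A/J ssRNA array 1, and fatty acid oxidation at 0.0594 and 0.169 without A/JOlaHsd saline array 3 and ssRNA array 3. Neutrophil markers stood at 0.178, 0.266 and 0.15 without A/J ssRNA arrays 1, 2 and 3 and at 0.0541 without A/JOlaHsd saline array 1. With no background correction, interferon-induced genes and neutrophil markers stood at 0.0964 and 0.213, and with no filter neutrophil markers stood at 0.525. With 18 arrays, fatty acid oxidation (0.515), mitochondrial respiration (0.169, with its direction reversed), neutrophil markers (0.544) and Toll-like receptor components (0.0535) ended.

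In saline legs, A/J and A/JOlaHsd differed in 2502 higher and 2801 lower genes, 5303 in all, in a comparison where strain and the lower signal of the A/JOlaHsd arrays go together. Lyz2 stood at 7.99 ± 0.43 (SD, n = 3) in A/J and 11.19 ± 1.30 in A/JOlaHsd, a difference of -3.19 ± 0.45 (SE, adjusted p = 4.72e-05). Lower in A/J were the matrix genes Thbs2 (-2.40 ± 0.26), Fn1 (-2.55 ± 0.42), Tnc (-2.26 ± 0.32) and Chad (-3.14 ± 0.37), chondroadherin of cartilage and tendon (adjusted p = 6.00e-06 to 0.000164). The 18 arrays gave 822 (594 higher and 228 lower). Median centring gave 7723 higher and 78 lower genes, with the median of all genes at 0.76. Of 1314 genes with more than 1 called probe, 515 (39.2%) had probes called in opposite directions.

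Among genes above background in both strains, the largest differences to the higher side in A/J saline legs were of Tmem64 (3.55 ± 0.17), Cmss1 (3.25 ± 0.28), Ccl27a (3.10 ± 0.23) and Bckdhb (3.01 ± 0.35), with adjusted p values of 9.15e-10 to 9.37e-06. Tomm22, of the mitochondrial import complex, Csrp1, Il6st, Cbwd1 and Mpeg1, not above background in A/JOlaHsd saline legs, were at least 24.7-fold, 11-fold, 7.65-fold, 5.68-fold and 5.11-fold higher (adjusted p = 7.97e-13 to 0.00868). The complex subunit genes Sdhd (2.36 ± 0.26) and Ndufb9 (2.02 ± 0.25) were higher as well (adjusted p = 5.61e-06 and 1.67e-05). Lower were Angptl7 (-2.51 ± 0.41), Ugt1a10 (-2.50 ± 0.33), Ms4a6d (-2.46 ± 0.44) and Myd88 (-1.04 ± 0.17), with adjusted p values of 2.55e-05 to 0.000347, and Ecrg4, not above background in A/J, was at least 5.58-fold lower (adjusted p = 5.32e-06). The difference of Myd88 was 0.33 with median centring. A second Myd88 probe went the other way (adjusted p over all probes = 0.00151), without a measure of size, since it was above background on 3 of 3 A/J and 0 of 3 A/JOlaHsd saline arrays. With 18 arrays, Lyz2, Mpeg1, Ms4a6d, Myd88, Ndufb9, Thbs2 and Ugt1a10 ended (adjusted p = 0.0712 to 0.523). Of the lists, matrix genes (21 of 38 lower and 1 higher, the same adjusted over the list alone, median -0.76, list adjusted p = 0.000174), macrophage markers (-0.77, 0.0186), fibroblast markers (-0.70, 0.0196), complement (-0.74, 0.0364, and 0.0510 with a replicate block) and proliferation (-0.48, 0.0364) were lower, and mitochondrial respiration (0.28, 0.0186) and glycolysis (0.42, 0.0397) higher. All 7 lost the call (adjusted p = 0.730 with an estimated correlation). Without A/J saline array 3, the list adjusted p was 0.0792 for complement and 0.0747 for proliferation, fibroblast, glycolysis, macrophage and mitochondrial genes. Without A/JOlaHsd saline array 3, it was 0.133 for proliferation, 0.0843 for complement, glycolysis and macrophage markers and 0.103 for mitochondrial genes, and without A/JOlaHsd saline array 2 it was 0.0574 for complement and glycolysis. Glycolysis stood at 0.0728 with no background correction, complement at 0.173 with no filter and 0.0513 with the stricter filter, and glycolysis and mitochondrial genes at 0.359 and 0.290 with 18 arrays.

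MyD88 deficiency without ssRNA was read in saline legs of A/J-MyD88 and A/J. Macrophage, proliferation, regeneration and matrix genes were higher in A/J-MyD88 as lists with the preset correlation. None was called with an estimated correlation (adjusted p = 0.0993 to 0.194). The same A/J saline arrays served for ssRNA in A/J, both response differences and both saline comparisons, so these results are not independent. Lyz2 stood at 10.83 ± 0.42 (SD, n = 3) against 7.99 ± 0.43 (2.84 ± 0.45 (SE), adjusted p = 0.00197). Trem2, a receptor of tissue macrophages, was higher by 2.43 ± 0.30 (adjusted p = 0.000383) and the intermediate filament gene Vim by 1.80 ± 0.18 (adjusted p = 7.55e-05). The test found 493 higher and 111 lower genes, 604 in all. Of these, 464 and 77 moved the same way with ssRNA in A/J (61.2 and 11.1 expected), and 2 and 0 the other way. The 18 arrays gave 15 (13 higher and 2 lower). The count was 214 without A/J saline array 3, and without A/J-MyD88 saline arrays 1 and 2 it was 365 and 179. It was 972 with median centring and 1036 with only the compared arrays.

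Lrrc2 showed the largest difference (4.35 ± 0.13, adjusted p = 3.86e-12), from 4.30 ± 0.11 (SD, with 1 of 3 arrays above background by any of its probes) in A/J to 8.65 ± 0.19 in A/J-MyD88. The probe used was not above background on any A/J saline array, so background limits the measured size. Ms4a6d (2.72 ± 0.44), the histone genes H2ac15 (2.37 ± 0.43), H2ac24 (2.37 ± 0.30) and H2ac12 (2.32 ± 0.32), Ankrd1 (2.32 ± 0.41), Gpnmb (2.31 ± 0.43), Prc1 (2.18 ± 0.35), Tnc (2.07 ± 0.32), Fn1 (1.78 ± 0.42), Ccl9 (1.73 ± 0.28), Myog (1.67 ± 0.34), Csrnp1 (1.58 ± 0.15), Timp1 (1.56 ± 0.30), C1qb (1.51 ± 0.33), Cdc20 (1.5 ± 0.20), Mcm5 (1.41 ± 0.16), Unc93b1 (1.36 ± 0.32), Mymk (1.31 ± 0.20), a gene of myoblast fusion, Tlr7 (1.27 ± 0.24), Ctss (1.25 ± 0.30), Thy1 (1.22 ± 0.23), Myd88 (0.71 ± 0.17) and Oxsr1 (0.65 ± 0.16) were higher too (adjusted p = 3.73e-05 to 0.0235). Lower were Rpe (-1.81 ± 0.49), Pnpla3 (-1.66 ± 0.39), Manbal (-1.46 ± 0.18), Higd1a (-1.38 ± 0.20), Crip3 (-1.34 ± 0.25), Atp5e (-1.34 ± 0.22), the clock gene Arntl (-1.27 ± 0.28) and Fkbp5 (-1.27 ± 0.29), a gene induced by glucocorticoids (adjusted p = 0.000383 to 0.0421). Dysf differed by 0.02 ± 0.14 (adjusted p = 0.969). In each called gene named here, the arrays of the strains did not overlap, which the largest differences had to meet to be named. Of these 35 calls, 23 held with any single array left out. With 18 arrays, 27 of the calls named for these legs ended (adjusted p = 0.245 to 1.00). With no background correction, Arntl, Ctss, Mymk, Oxsr1, Pnpla3 and Rpe ended (0.0515 to 0.201), and with no filter, Ctss, Fkbp5, Fn1, Pnpla3, Rpe and Unc93b1 (0.0504 to 0.118). Without A/J-MyD88 saline array 2, C1qb, Ctss, Fkbp5, Fn1, Myd88, Myog, Oxsr1, Pnpla3, Rpe, Timp1 and Unc93b1 ended (adjusted p = 0.0514 to 0.163). Without A/J saline array 3, C1qb, Ctss, Fkbp5, Fn1, Myd88, Myog, Oxsr1, Pnpla3 and Unc93b1 ended (0.0620 to 0.146). Without A/J-MyD88 saline array 1, Arntl, Fkbp5, Fn1, Oxsr1, Pnpla3 and Rpe ended (0.0568 to 0.0982), and without array 3, Myd88, Oxsr1 and Rpe (0.0724 to 0.0974). Without A/J saline array 1, Arntl, Oxsr1 and Rpe ended (0.0605 to 0.179), and without array 2, Fkbp5, Fn1, Myd88, Pnpla3 and Rpe (0.0581 to 0.133).

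Of the lists, 11 differed between these saline legs. Macrophage markers (20 of 30 higher, 23 adjusted over the list alone, median 1.46, list adjusted p = 3.24e-22), proliferation (13 of 26, 17, 0.79, 6.77e-18), matrix genes (15 of 38, 24, 0.69, 4.09e-15), regeneration (7 of 24, 11, 0.60, 1.21e-08), antigen presentation (1.99e-05), cytokines (4.44e-05), Toll-like receptor components (0.000258), fibroblast markers (0.000531), complement (0.00165) and inflammasome components (0.00441) were higher. Mitochondrial respiration was lower (0 of 44 genes called, median -0.20, 5.03e-07). Interferon-induced genes were not called (0.761), nor were neighbours of Myd88 (0.833). No list kept its call with an estimated correlation (adjusted p = 0.0993 to 0.248).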

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

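The test on probe directions in saline legs and the test on other cell types in A/J were chosen after the results they concern had been seen, and the comparison of responses was planned.

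The response to ssRNA differed between strains by a direct test of the difference. Between A/J and A/JOlaHsd, 850 genes differed. The response was higher in A/J for Ifi27l2a (3.16), Lyz2 (2.94), Ms4a6d (2.85), Gpnmb (2.85), Gal (2.84), H2ac12 (2.68), Tnc (2.67), Tyrobp (2.66), Ctss (2.53), Fn1 (2.52), C1qb (2.38), Ccl7 (2.20), Ccl9 (2.17), Col1a1 (2.09), Prc1 (2.06), Top2a (2.00), Lgals3bp (1.73), Tlr7 (1.44) and Myd88 (0.91), in log2 units. It was lower for Wscd1 (-1.59), Asb12 (-1.57), Otud6b (-1.53), Leo1 (-1.51), Fitm1 (-1.5), Smc3 (-1.49), S100a14 (-1.36) and Wnt4 (-1.34). Gal and Ccl7 were not above background in A/JOlaHsd ssRNA legs, nor Top2a in A/J saline legs, so their values do not measure the size of the difference. For Lyz2 and Tnc, the A/J saline arrays lay below all A/JOlaHsd saline arrays, while the ssRNA arrays of the strains overlapped. Their larger response in A/J was thus not a higher level after ssRNA. For Ctss, saline arrays overlapped and the A/J ssRNA arrays lay higher. With 18 arrays, 5 genes differed, and all the calls named here ended.

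Between A/J-MyD88 and A/J, the responses of 1144 genes differed. The response was lower in A/J-MyD88 for Ccl8 (-4.03), Ms4a6d (-3.79), Lyz2 (-3.74), H2ac12 (-3.65), Ifi27l2a (-3.64), H2ac15 (-3.63), Ms4a7 (-3.53), Ctss (-3.37), Ccl9 (-2.92), Tnc (-2.91), Tlr7 (-2.20), H2-D1 (-2.17), Psmb8 (-2.17), Klrd1 (-2.15), Lgals3bp (-2.01), Tlr2 (-1.99), Cdc20 (-1.80), Mcm5 (-1.64), Nkg7 (-1.37), Ifitm3 (-1.35) and Myd88 (-1.17). It was higher for Slc16a3 (1.65), Pdk2 (1.6), Fitm1 (1.48), Chrne (1.47), Decr1 (1.42), Slc38a3 (1.4), Crat (1.34) and Lrtm1 (1.32). Nkg7 was not above background in A/J saline legs, so its value does not measure the size of the difference. Of 100 drawn splits of the legs within each strain, the real one included, 6 gave as many genes, a share that is not under 0.05, and the highest of the others gave 1457. The 5 others with as many were among 13 that kept the A/J legs as labelled (653 to 1457 genes), and the 86 that regrouped the A/J legs gave 0 to 5. The count followed the grouping of the A/J legs, so the share over all splits decides little.

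A signal was also present in data outside the gene comparisons. Of 3333 detected probes without a gene name, 53 were higher and 32 lower in ssRNA legs of A/JOlaHsd, 289 were higher and 195 lower in those of A/J, and 0 were called by limma in A/J-MyD88 (28 unadjusted).

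The rise of macrophage markers in A/J legs given ssRNA was weighed against a lower share of muscle fibre RNA, which would raise the markers of other cell types alike. The median log2 fold change was 2.59 for macrophage markers, with a lower quartile of 1.96, and -0.14 for endothelial, -0.23 for smooth muscle and -0.19 for Schwann cell markers. Fibroblast, neutrophil, T and NK cell and B and plasma cell markers had medians of 0.65, 0.62, 0.51 and 0.33, and adipocyte markers -0.05. All these medians lay below the lower quartile of the macrophage markers, which argues against a lower share of fibre RNA as the whole cause. A part of it in the rise was not ruled out. More macrophages in the tissue or more transcript per macrophage stay open, and neither was tested.

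The 5303 genes between A/J and A/JOlaHsd saline legs were weighed against arrays read at different signal. Of genes with more than 1 called probe, 39.2% (515 of 1314) had probes called in opposite directions, against 0.632% (3 of 475) for ssRNA within A/J (Fisher's exact test, p = 1.12e-78). A technical difference between the arrays of these strains may therefore account for part of these genes. Strain differences, dysferlin included, stay open, since all A/JOlaHsd arrays had lower signal and the labels name no run. For Dysf, 3 probes were lower and 1 was higher in A/J.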

How the results depend on the processing

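All alternatives but the normalization of each strain alone were planned, and the values in the report, from 17 arrays, were themselves chosen after the data had been seen. For each change of a value given here, the cause was not tested, except that leaving out an array or a filter changes the arrays or genes tested.

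With all 18 arrays, as planned, 28 genes were called in A/JOlaHsd (213 with 17), 220 in A/J (2518), 0 in A/J-MyD88 (0), 5 for the response of A/J against A/JOlaHsd (850), 25 for that of A/J-MyD88 against A/J (1144), 822 and 15 in saline legs for A/J against A/JOlaHsd and A/J-MyD88 against A/J (5303 and 604), and 18 in ssRNA legs of A/J-MyD88 against A/J (636). The median of all genes stood at -0.39 in A/JOlaHsd and 0.38 for the response of A/J against A/JOlaHsd. Of 234 gene values, 86 kept direction and call, 145 lost the call and 3 reversed. These were Dysf (1.44, A/J against A/JOlaHsd response), and Myd88 (-1.0) and Psmb10 (-0.33) in A/JOlaHsd. Of 93 list calls, 72 held, 20 were lost and 1 reversed, mitochondrial respiration for the response of A/J against A/JOlaHsd (adjusted p = 0.169).

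In A/JOlaHsd, the count was 0 in limma with the authors' values (452 unadjusted), with each strain normalized alone (510), with median centring (730) and with only the arrays compared (253). It was 342 with no background correction, 435 with no filter and 468 with every probe. For the response of A/J against A/JOlaHsd, the count was 1394 with the authors' values, 1754 with median centring and 187 with only the arrays compared (156 higher and 31 lower). For that of A/J-MyD88 against A/J, these gave 2131, 1764 and 2174. Every probe gave 9246 for A/J against A/JOlaHsd saline legs. For A/J-MyD88 against A/J, median centring and only the arrays compared gave 972 and 1036 in saline legs and 1247 and 1259 in ssRNA legs, and no background correction gave 166 in ssRNA legs. Over the settings other than all 18 arrays and leaving out 1 array, the count of A/J ranged from 2014 to 3774 and that of A/J-MyD88 was 0 in limma throughout (131 unadjusted with 17 arrays).

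Of the gene values, 204 of 234 kept direction and call with median centring, 201 of 234 with no background correction, 217 of 234 with no filter, 233 of 234 with the stricter filter, 202 of 229 with only the arrays compared, 134 of 154 with the authors' values and 77 of 96 with each strain normalized alone. Median centring reversed Dysf (0.14, response of A/J against A/JOlaHsd) and Myd88 (0.33, A/J against A/JOlaHsd saline legs), and no background correction reversed Wdr82 (-0.62, A/J-MyD88 against A/J ssRNA legs). Further probes of Dysf and Myd88 were read from the 17 arrays alone. Of 78 list calls of the planned comparisons, 14 held with an estimated correlation.

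Leaving out 1 array gave 289 to 516 genes in A/JOlaHsd, where a group left with 1 array is assumed to vary like the others, and 1537 to 2400 in A/J. It gave 307 to 1306 for the response of A/J against A/JOlaHsd, 599 to 1222 for that of A/J-MyD88 against A/J, 4556 to 5488 for A/J against A/JOlaHsd saline legs, and 179 to 532 and 187 to 393 for A/J-MyD88 against A/J saline and ssRNA legs. Of 1692 gene values, 1543 kept direction and call, 137 lost the call, 3 gained it and 9 reversed. Those that reversed in at least 1 case were Dysf in A/JOlaHsd (-0.25 to 0.047), in A/J-MyD88 (-0.15 to 0.11) and between A/J-MyD88 and A/J saline legs (-0.10 to 0.16), and Myd88 in A/J-MyD88 (-0.066 to 0.22), none of which was called. Matrix genes in A/J-MyD88 ranged from a list adjusted p of 5.98e-05 to 0.423, reversed at the latter.

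The replicate block, which treats equal numbers as paired legs, moved no count by more than 1.5 times and gave 76 list calls in the planned comparisons, against 78. Among the genes named and the 93 lists called, it ended 5 gene calls and 8 list calls and added 1 gene call, each given with its result. It also called 6 lists that were not called without it, adipocyte markers in A/JOlaHsd (adjusted p = 0.0268), adipocyte and smooth muscle markers for the response of A/J against A/JOlaHsd (0.0391 and 0.0137), glycolysis for that of A/J-MyD88 against A/J (0.0476), and slow fibre genes and neighbours of Myd88 in ssRNA legs of A/J-MyD88 against A/J (0.0272 and 0.0203). It changed no other named gene or list, while calls of genes not named moved with the counts. A block by chip was not run, because the files name no chips, and the authors' values were not used between strains. Low signal limits the A/JOlaHsd arrays, which detected 28.9% to 33.2% of probes.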

Other observations

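The comparison of ssRNA legs, the test of genes around Myd88 and the donor segment as its explanation were chosen after the data had been seen.

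In legs given ssRNA, antigen presentation genes and T and NK cell markers were lower in A/J-MyD88 than in A/J, as were single chemokine and interferon-induced genes. Ccl8 was lower by -2.71 ± 0.28 (SE, n = 3 in each group, limma adjusted p = 5.89e-05), Ccl5 by -2.01 ± 0.21 (adjusted p = 5.89e-05), Ifi27l2a by -2.33 ± 0.30 (adjusted p = 0.000449) and Klrd1 by -1.90 ± 0.17 (adjusted p = 7.38e-06). Mpeg1 (-3.71 ± 0.81), Plac8 (-2.73 ± 0.35), Fcgr4 (-2.31 ± 0.33), Ctss (-2.12 ± 0.30), H2-K1 (-2.08 ± 0.31), Psmb8 (-1.73 ± 0.24), Irf7 (-1.69 ± 0.33), Oasl2 (-1.50 ± 0.41) and Nkg7 (-1.36 ± 0.16) were lower too (adjusted p = 0.000131 to 0.0446), and Fpr2, not above background in A/J-MyD88, was at least 3.4-fold lower (adjusted p = 3.53e-06). Myl3 (2.81 ± 0.28), Wdr82 (1.62 ± 0.10), Pdk4 (1.39 ± 0.24), which limits glucose oxidation, Csrnp1 (1.38 ± 0.15) and Decr1 (0.85 ± 0.19) were higher (adjusted p = 8.84e-08 to 0.0177), and Lrrc2, not above background in A/J, was at least 16.6-fold higher (adjusted p = 5.73e-12). Wdr82 stood at -0.62 with no background correction. Dysf and Myd88 differed by 0.44 ± 0.14 (adjusted p = 0.0761) and -0.45 ± 0.17 (adjusted p = 0.124), while a second Myd88 probe was lower by -0.49 ± 0.13 (adjusted p over all probes = 0.0489). In each called gene named here the arrays of the strains did not overlap. The test found 297 higher and 339 lower genes, 636 in all. With 18 arrays it found 18 (4 higher and 14 lower), with median centring 1247 (89 higher and 1158 lower), with only the compared arrays 1259 and with no background correction 166. Without A/J ssRNA arrays 1, 2 and 3 it found 256, 393 and 187, and without A/J-MyD88 ssRNA arrays 1, 2 and 3 it found 332, 189 and 290. With no background correction, 10 of the genes named here ended (Csrnp1, Decr1, Fcgr4, Irf7, Klrd1, Mpeg1, Nkg7, Oasl2, Plac8 and Wdr82, adjusted p = 0.0523 to 0.789), with no filter Oasl2 (0.0953), and with 18 arrays 12 (0.103 to 1.00), while Dysf was called with only the compared arrays (0.0354). Oasl2 stood at an adjusted p of 0.165, 0.0714 and 0.0649 without A/J arrays 1, 2 and 3 and 0.130 and 0.154 without A/J-MyD88 arrays 1 and 2, Mpeg1 at 0.0560 without A/J array 3 and 0.0867 and 0.0678 without A/J-MyD88 arrays 2 and 3, and Decr1 at 0.0754 and 0.0520 without A/J arrays 1 and 3 and 0.0858 and 0.0689 without A/J-MyD88 arrays 2 and 3.

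In the same legs, 15 of 29 lists were called with the preset correlation, 2 with an estimated correlation and 13 with fry. Antigen presentation (12 of 27 lower, 20 adjusted over the list alone, median -0.79, list adjusted p = 2.95e-16) and T and NK cell markers (5 of 17 lower and 1 higher, 7 and 1 adjusted over the list alone, median -0.29, list adjusted p = 3.97e-06) kept their calls (adjusted p = 0.0387 and 0.00754 with an estimated correlation). Macrophage markers (12 of 30, median -0.93, 4.65e-16), interferon-induced genes (7 of 32, -0.76, 9.34e-12), cytokines (1.52e-08), complement (1.35e-05), Toll-like receptor components (9.49e-05), proliferation (0.000199), neutrophil markers (0.000263), fibroblast markers (0.00480), matrix genes (0.00700) and inflammasome components (0.0118) were lower, and fatty acid oxidation (0.0162), smooth muscle (0.0370) and mitochondrial genes (0.0446) were higher. These 13 lost the call (adjusted p = 0.0805 to 0.630 with an estimated correlation). With the replicate block, smooth muscle stood at 0.0510 and mitochondrial genes at 0.0600. They stood at 0.0548 and 0.0643 with median centring, 0.0506 and 0.0627 with the stricter filter and 0.173 and 0.816 with 18 arrays, and mitochondrial genes at 0.0564 with no background correction and 0.0616 with only the compared arrays. Without A/J ssRNA arrays 1 and 2, mitochondrial genes stood at 0.0714 and 0.219. Inflammasome components ended without array 1 (0.0556), neutrophil markers without array 2 (0.0593), and fibroblast markers and smooth muscle without array 3 (0.0528 and 0.102). Without A/J-MyD88 ssRNA array 1, matrix genes (0.0832), fatty acid oxidation (0.0658), mitochondrial genes (0.380) and smooth muscle (0.0502) ended, without array 2 fatty acid oxidation (0.0504), and without array 3 smooth muscle (0.0683).

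Genes that lie near Myd88 on chromosome 9 differed between A/J-MyD88 and A/J in both legs. The window held the 100 nearest tested genes on each side in the gene order of GRCm38.p6, cut short where the chromosome ended, 143 in all. Of 11068 other genes, 14 (0.126%) were called in the same direction in both legs, 6 of them among 496 genes on the rest of chromosome 9. In the window, 11 (7.69%) were so called (Fisher's exact test against all other genes, p = 3.77e-15). They were 6430571L13Rik, Nicn1, Myl3, Lrrc2, Ccrl2, Cmtm8, Stt3b, Azi2, Oxsr1, Acaa1a and Csrnp1, named after their values were seen, with 7 higher and 4 lower. A donor segment carried with the targeted Myd88 allele may account for them. Whether A/J and A/JOlaHsd share alleles that A/J-MyD88 lacks was not decided. The median absolute log2 difference between A/J and A/JOlaHsd saline legs was 0.29 for these genes and 0.39 for all genes, but the genes were chosen by their difference between A/J-MyD88 and A/J. Of 5 of these genes with further probes, none had one called in the same direction in saline legs. The second probe of Cmtm8 differed by -0.73 (adjusted p = 0.131) and its main one by -0.65, while those of Nicn1, Stt3b, Azi2 and Oxsr1 differed by -0.19 to 0.11. A strain variant under the probe stays open.

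A comparison of 3 against 3 arrays has 10 splits, the real one included, too few for a share under 0.05. The real split gave 2518 genes in A/J, 5303 and 604 in saline legs and 636 in ssRNA legs, as many as in 1 of 10 splits each, and the highest of the others gave 3, 0, 0 and 0. In A/J-MyD88, the real split gave 0 genes in limma (131 unadjusted), as did all 10 splits, with 0 the highest of the others. Comparisons with 2 ssRNA arrays of A/JOlaHsd were not split.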
